A study of Mus musculus with 3 samples.

How the data were processed

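The data were the deposited count matrices of 3 libraries of mouse jaw cells: Ctrl, 1d and 7d, the latter 2 killed 1 or 7 days after 10 Gy to the head and neck. Each library pooled 8 mice, per the labels' protocols, so every group had 1 library. There were no replicates and no test between groups, and every interval below covers counting error only. The values were counts of unique molecular identifiers (UMIs) per gene and cell, as the deposited files hold them and per the file headers. Tissue was minced, digested with collagenase II, frozen and later thawed, per the labels' protocols. Reads were handled with CASAVA 1.8, Cell Ranger and Seurat and placed on mm10, per the submitters' processing notes. Cell Ranger was version 6.1.1, per the file headers. The alignment settings, the annotation release and the rule that called cells are not given in the sources used here.

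The cell filter, marker lists, gene lists, list statistics and most alternatives were fixed before the data were examined. The rules that name clusters, the rule for the mesenchymal pool and the comparison of single clusters were set after the data were seen.

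Cells were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs. Doublets were called per library with Scrublet as held in scanpy. Its automatic threshold removed 293 cells (3.30%) of Ctrl. In 1d and 7d that threshold called under 0.5% of cells, so the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes: 248 (4.84%) and 403 (6.20%). Counts were scaled to 10000 per cell and logged. The top 2000 variable genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1. No correction between libraries was applied.

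The 35 clusters were named from markers of 32 classes. A cluster took a name where at least 3 markers had a log2 of 1 or more against all other cells and were detected in at least 10% of its cells. It also needed 3 of them among its top 10 genes, or 2 with a mean log2 of at least 0.95, or a mean of at least 1.5 with 60% of the markers passing. Clusters led by markers of another lineage stayed unnamed. This named 31 clusters in 19 classes, and each class name stands for "-like" cells. No cluster met the rule for mesenchymal stromal cells. The mesenchymal pool therefore joined periodontal ligament and tendon, fibroblast and osteoblast clusters with unnamed clusters whose best lineage was mesenchymal by a margin of at least 1 log2.

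Shares were cells of a class over all kept cells, with exact 95% intervals. UMIs were summed over the cells of a class, and ratios of counts per 1000000 UMIs carried exact 95% intervals. Classes with at least 30 cells in both libraries were compared. Where one side was 0, its share and the ratio were given at a floor of 3 counts. The interval of such a ratio used the 0 itself and not the floor. Genes were named by a fixed rule: those furthest from a ratio of 1 by the nearer end of the interval, up to 5 per side in the pool and up to 3 per side in B cells, neutrophils and T cells. In the library where it was higher, a gene had to be detected in at least 10% of the class's cells. There, no cell could hold over 20% of the class's UMIs of it. Its counts per 1000000 UMIs in the class also had to reach those over that whole library. Haemoglobin, immunoglobulin, mitochondrially encoded and ribosomal protein genes, gene models such as Gm and Rik, Xist, Tsix and Y-linked genes were left out. The rule added 12 genes of taurine, p53, oxidative stress and bone biology. List examples were the members furthest from 1 among those with at least 20 UMIs over the 2 libraries, without the rules on detection and single cells.

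The 20 gene lists were p53 targets, NRF2 targets, taurine metabolism and transport, DNA repair, senescence, osteogenic, adipogenic, haematopoietic niche, extracellular matrix, interferon response, NF-kB and inflammatory, apoptosis, MHC class II, S phase, G2/M phase, neutrophil granule, dissociation and immediate early, mitochondrially encoded, glycolysis and hypoxia, and haemoglobin. Some genes sit in more than one list. A list needed at least 5 members with at least 20 UMIs over the 2 libraries. Its result was the median log2 ratio with a pseudocount of 0.5, an interval from 1000 Poisson redraws, and a percentile among 10000 random lists drawn within 20 bins of abundance. The percentile ranks a list among genes and is not a test between groups. Cycling cells held UMIs of at least 2 of 6 cycling genes after thinning each cell to 1000 UMIs.

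Alternatives were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), no filter, doublets kept, Leiden resolution 0.5 and 2, a denominator without neutrophil, neutrophil precursor and erythroid cells, clustering without p53, interferon and dissociation genes, TMM factors, thinned cells, 5% free RNA subtracted, list members with at least 5 or at least 100 UMIs, cycling cells not thinned, and cycling cells with 1 of 6 genes. A comparison within the 1 cluster best shared by the libraries was added after the data were seen, for T cells later than for the pool, B cells and neutrophils. In the pool that cluster was 19, with 26.4%, 30.7% and 49.4% of its cells in Ctrl, 1d and 7d.

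Simulated counts were Poisson draws from 1 shared profile of the pool for each pair of libraries, without differences between cells or in cluster makeup. The rates that follow therefore cover counting error only. In these counts the interval held the true ratio for 96.2% of 11920 genes in 1d compared to Ctrl and for 96.5% of 11644 genes in 7d compared to Ctrl. Genes changed 2-fold were recovered at 83% and 60%, and genes changed 4-fold at 95% and 86%. Of unchanged genes, 3.94% and 3.77% had intervals that left out 1. A list raised 2-fold gave 0.98 and 0.96, both at percentile 100. A single unchanged list gave −0.14 at percentile 1.08 in 1d and 0.00 at percentile 53.1 in 7d. After that was seen, 200 unchanged lists were drawn: 8 (4%) for 1d and 5 (2.5%) for 7d fell outside the central 95% of percentiles.

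Of 31253 gene identifiers, 31107 (99.5%) were found in GENCODE M21 on GRCm38, which gave the positions (first and last base, counted from 1). Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. The random seed was 7.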

Results

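Jaw cells from 3 libraries, Ctrl, 1d and 7d, gave 8587, 4879 and 6094 cells. Neutrophil-like cells were the largest class in Ctrl and T cell-like cells in 7d, and B cell-like cells and neutrophil precursors were close to each other in 1d. Cells of mesenchymal lineage were a small part. The latter 2 libraries came from mice killed 1 or 7 days after 10 Gy to the head and neck. There was 1 library per group, so there were no replicates and no test, and intervals (95%) cover counting error only. Cells carried a median of 2412, 5022 and 3816.5 UMIs and 1031, 1541 and 1376 genes. The filter removed 2435, 916 and 1247 barcodes, of which 2349, 756 and 1094 had over 50% haemoglobin UMIs. Xist, the RNA of the silenced X chromosome of females, had 10, 6 and 13 UMIs, while the Y-linked gene Ddx3y had 4525, 3306 and 4210, as in male mice.

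In the library labelled 1d, precursors of blood cells made up more of the cells and mature neutrophils, T cells and NK cells made up less than in Ctrl. Neutrophil precursors were 2.07% of cells in Ctrl and 24.2% in 1d, a ratio of 11.7 (9.98 to 13.8), while mature neutrophils were 34.1% and 13.6% (ratio 0.399; 0.799 with no filter). B cell precursors were 0 of 8587 cells in Ctrl (0.0349% at a floor of 3 cells) and 5.76% in 1d. That was 165-fold higher against the floor, with a counting interval, which uses no floor, from 133. The 0 is that of the named cluster alone. At least 2 UMIs of 4 precursor genes (Vpreb1, Igll1, Rag1 and Dntt) were held by 11 kept cells of Ctrl and 543 of 1d. Monocytes (6.98-fold; 2.87 with no filter), haematopoietic stem and progenitor cells (6.68-fold; log2 2.74, or 3.70 at Leiden resolution 2) and plasmacytoid dendritic cells (4.87-fold) were also higher. The only cluster of stem and progenitor cells, cluster 18, was led by Pf4 and Itga2b and had a higher mean log2 for megakaryocyte markers (1.87) than for its own (1.62). Erythroid cells were 19.2-fold higher, but with no filter the ratio was 0.715. T cells were 15.3% and 3.44%, and NK and innate lymphoid cells were 6.49% and 0.984%. B cells were 21.3% and 25.7%, but different clusters held them. Cluster 0 had 1639 of 1831 B cells in Ctrl and 287 of 1253 in 1d. Cluster 6, with Rag1 among its leading genes, had 11 and 888, so the higher share in 1d rested on cluster 6. With doublets kept, the log2 ratio of the B cell share was −1.56 instead of 0.27, and Rag1 and Gfra1 gave no value in B cells. Macrophages were 5.16% and 4.76%, with ratios from 0.499 to 1.45 over the alternatives, and mast cells (1.52-fold) and conventional dendritic cells (1.47-fold) were slightly higher.

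In the library labelled 7d, T cells and NK cells made up a larger part of the cells than in Ctrl, and mature neutrophils were scarce. T cells were 31.0% of cells, 2.02 times Ctrl (1.89 to 2.17), and NK cells were 17.9%, 2.76 times Ctrl (2.49 to 3.06). Mature neutrophils were 3.72%, a ratio of 0.109 (0.0949 to 0.125; 0.184 with no filter), while neutrophil precursors were 10.6% (5.12-fold) and monocytes 9.22% (8.90-fold; 1.91 with no filter). B cells were 8.12% (0.381) and macrophages 0.722% (0.140; log2 ratio −2.84, but 0.10 with no filter and −0.020 at Leiden resolution 0.5). B cell precursors were 2.23%, 63.9-fold above Ctrl on the same floor, with a counting interval, which uses no floor, from 51.2. These values are for the named cluster alone: by the 4 precursor genes, 11 kept cells of Ctrl and 220 of 7d were counted. Erythroid cells were 6.12% of cells compared to 0.105% in Ctrl, a class most affected by the filter on barcodes: with no filter the log2 ratio was −0.035 instead of 5.87. Stem and progenitor cells (7.92-fold; 17.7 at Leiden resolution 2), plasmacytoid (3.25-fold) and conventional (2.04-fold) dendritic cells and mast cells (2.65-fold) were higher.

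**Figure D1:**
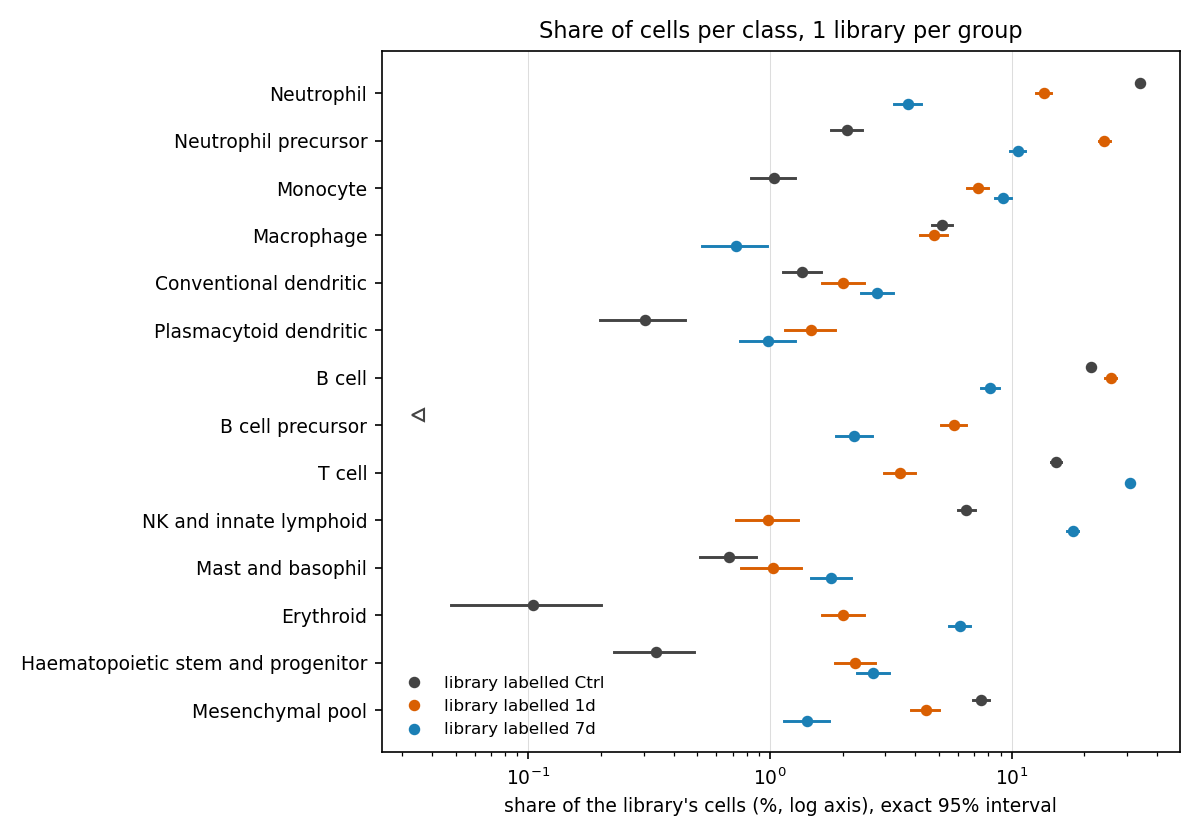
Share of each cell class in the libraries labelled Ctrl, 1d and 7d, with 95% intervals. Intervals cover counting error only.

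The mesenchymal pool made up less of the cells of 1d and 7d, going from 7.49% (6.94 to 8.07) in Ctrl to 4.41% (3.85 to 5.02) in 1d and 1.43% (1.15 to 1.76) in 7d. Its periodontal ligament and tendon cells went from 1.98% to 1.35% and 0.706%, and fibroblasts from 1.83% to 0.451% and 0.328%. Osteoblasts numbered 48, 7 and 0 cells, or 0.559%, 0.143% and 0 (0.0492% at a floor of 3 cells). However, removal as doublets had taken 0 of 40, 7 of 18 and 6 of 8 cells rich in Bglap and Bglap2. Endothelial cells were 0.675%, 0.184% and 0.394%, and epithelial cells 0.722%, 0.471% and 0.0164%. The pool was made of 643, 215 and 87 cells. Cluster 19, of ligament and tendon cells, held 26.4%, 30.7% and 49.4% of them, and cluster 25 held 110, 52 and 2 cells. Unnamed clusters outside the pool held 231, 0 and 17 cells, or 2.69%, 0 (0.0615% at a floor of 3 cells) and 0.279%. One of them, cluster 23, carried Ctsk, Acp5 and Col12a1 and had 226 cells in Ctrl and 0 in the other 2 libraries.

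Targets of p53, the factor that answers DNA damage, were lower in the pool of 1d than in that of Ctrl. The median log2 ratio of 35 genes was −1.02 (−1.22 to −0.80), with 25 lower and 10 higher, and it lay at percentile 0 of random lists. Eda2r, a receptor of the tumour necrosis factor family, had 3 UMIs in 1d and 262 in Ctrl (ratio 0.0333, 0.00681 to 0.0983), and Psrc1, a spindle gene, had 1 and 99 (0.0293, 0.000735 to 0.167). Ccng1, cyclin G1, was at 0.133 (0.0932 to 0.185), Mdm2, the ligase that degrades p53, at 0.224 (0.192 to 0.259), and Cdkn1a, the inhibitor p21, at 0.418 (0.393 to 0.445). Over the alternatives Eda2r reached up to 0.107, Ccng1 up to 0.309, Mdm2 up to 0.260 and Cdkn1a down to 0.282. Cdkn1a (ENSMUSG00000023067) lies on chromosome 17 at 29090976 to 29100727, Mdm2 (ENSMUSG00000020184) on chromosome 10 at 117688875 to 117710758, and Ccng1 (ENSMUSG00000020326) on chromosome 11 at 40748552 to 40755311. Eda2r (ENSMUSG00000034457) lies on chromosome X at 97333840 to 97377216.

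**Figure D2:**
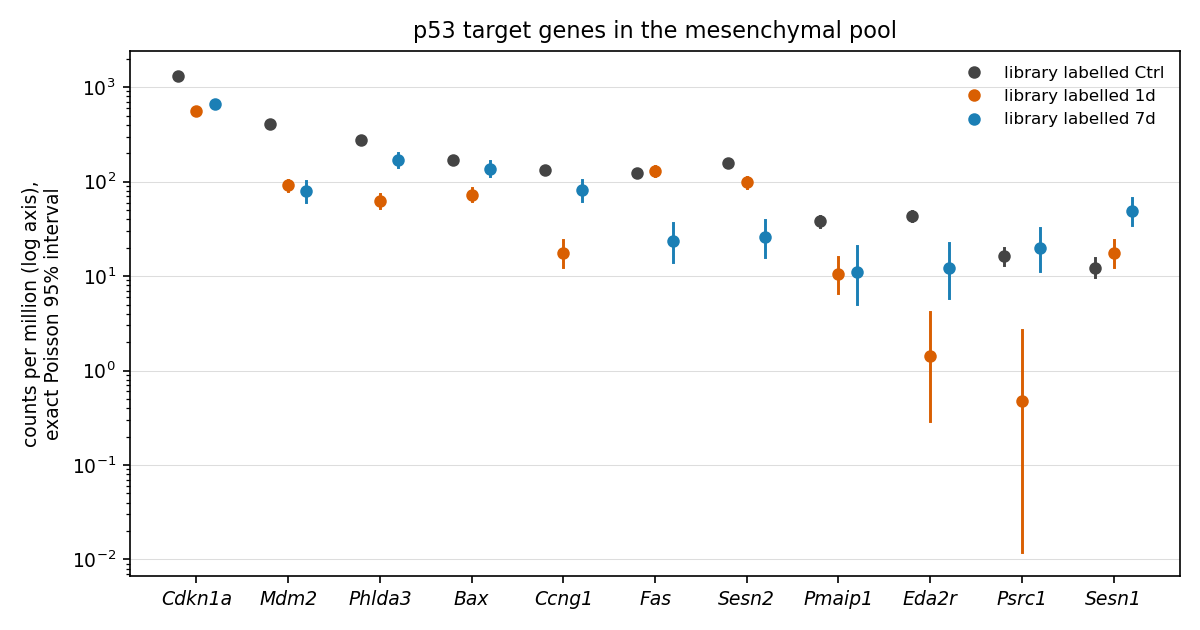
Counts of p53 target genes per 1000000 UMIs in the mesenchymal pool of the libraries labelled Ctrl, 1d and 7d, on a log axis. Bars show 95% counting intervals.

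The same list was lower at 1d in nearly every class compared. It was at −1.46 in neutrophil precursors (31 of 31 genes lower), −1.11 in neutrophils, −1.16 in periodontal ligament and tendon cells, −0.74 in mast cells, −0.66 in NK cells, −0.60 in conventional dendritic cells, −0.45 in monocytes and −0.41 in macrophages. T cells were at −0.20 (−0.36 to 0.07). B cells were the exception at 0.30 (0.01 to 0.40), and within cluster 0 alone they were at −0.37.

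**Figure D3:**
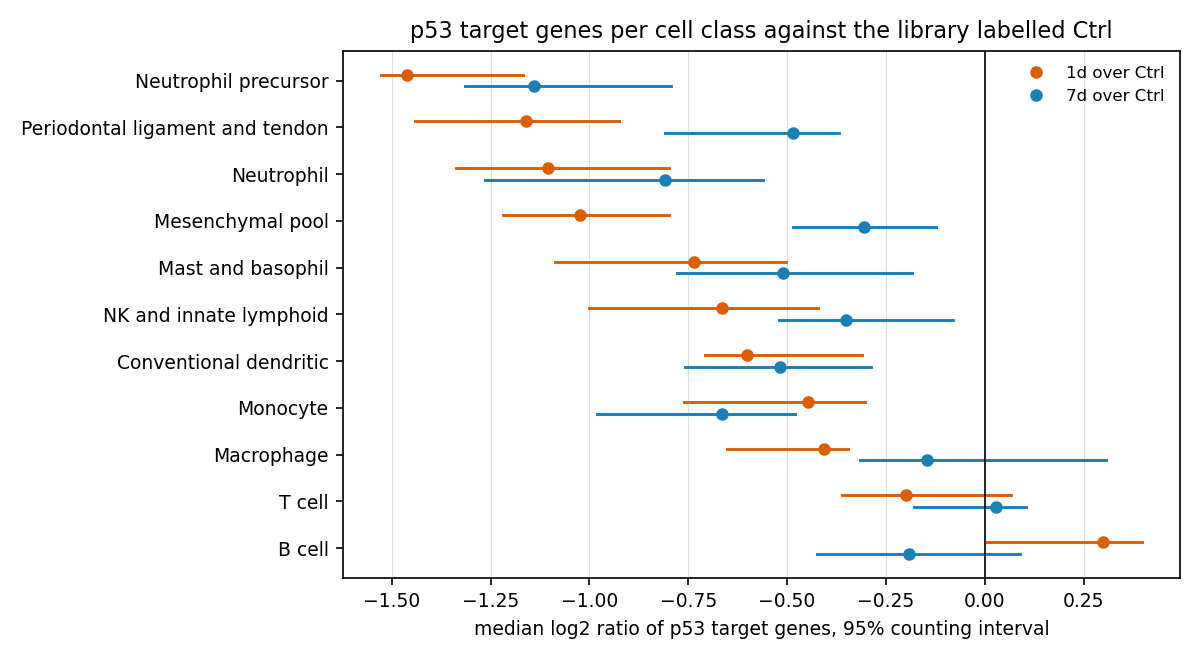
Median log2 ratio of p53 target genes per cell class between the libraries. Intervals cover counting error only.

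Beyond p53 targets, the pool of 1d held more RNA of Cldn10 and several signalling genes and less of Il6 and Mustn1. Cldn10, a tight junction claudin (ENSMUSG00000022132, chromosome 14, 118787908 to 118875489), was at 3.58 (3.10 to 4.13), Hhip, which binds hedgehog ligands, at 3.69 (1.53 in thinned cells), the neuronal vesicle gene Nsg2 at 4.53 (1.00 within cluster 19 alone) and neurotrophin Ntf3 at 4.22. Il6, an inflammatory cytokine (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), was at 0.194 (0.151 to 0.245), and Mustn1, a gene of muscle and bone repair that was also among the leading genes of the osteoblast cluster (48 and 7 cells), at 0.148. Over the alternatives Cldn10 went up to 7.39, Ntf3 down to 2.41, Il6 up to 0.399 and Mustn1 up to 0.363. Cxcl12, which holds stem cells in the marrow, was at 1.796 (1.66 to 1.94), the leptin receptor Lepr at 0.906 (0.631 to 1.28; 0.401 in thinned cells and 1.74 within cluster 19), the osteoblast factor Runx2 at 0.971 and the fat cell factor Pparg at 1.17 (0.671 to 1.98).

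Most other lists in the pool of 1d moved little. The osteogenic list was at −0.14, with Dmp1 at 0.114 and Bglap at 0.298, after doublet removal had taken 7 of 18 cells rich in Bglap and Bglap2 from 1d and 0 of 40 from Ctrl. The senescence list was at −0.13, with Ccl4 at 0.147 and Ccl5 at 0.149. The interferon list was at 0.34 (21 of 31 genes higher; 0.057 in thinned cells), although Cxcl9 was at 0.228, and DNA repair at 0.31, with Lig4 at 2.66 and Ddb2 at 2.18. Niche (−0.02), extracellular matrix (−0.01), NF-kB (0.01), apoptosis (0.05), adipogenic (0.12), S phase (−0.06), mitochondrially encoded (0.02) and glycolysis (0.11) genes were near 0, but in thinned cells NF-kB genes were at −0.52, and within cluster 19 apoptosis genes were at −0.44. Adipoq was nevertheless at 23.8 (9.42 to 77.2), with 41 UMIs against 5, Bmf at 6.17 and Postn at 1.82. G2/M genes were at 0.23 and dissociation genes at 0.22. Genes of other cells were lower: MHC class II at −0.75, neutrophil granule genes at −0.42 and haemoglobin at −3.34, but with doublets kept these were 0.76, 0.58 and 0.23.

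In the pool of 7d, genes of the extracellular matrix were higher and inflammatory genes lower than in Ctrl. The matrix list was at 1.07 (0.94 to 1.18; 0.73 with TMM factors), with 30 of 35 genes higher: Col3a1, a fibrillar collagen, at 5.66 (5.53 to 5.79), Fmod, which binds collagen fibrils, at 4.55, Postn, a ligament protein, at 4.37 and Col15a1 at 3.53. NF-kB and inflammatory genes were at −1.46 (−1.80 to −1.32), with 29 of 32 lower, among them Il6 at 0.0599 and Lcn2 at 0.0573. Lcn2 is also in the granule list. The neutrophil gene S100a8 went from 1065 counts per 1000000 UMIs in the pool of Ctrl to 55.3 in 7d. The part of neutrophil RNA in the fall of Lcn2 was not tested. Genes of other cells were lower too: MHC class II at −2.48 (−1.29 within cluster 19), granule genes at −2.80 (−1.24 within cluster 19) and haemoglobin at −2.58 (−8.83 with free RNA subtracted). Col3a1 (ENSMUSG00000026043) lies on chromosome 1 at 45311538 to 45349706, Fmod (ENSMUSG00000041559) on chromosome 1 at 134037254 to 134048277 and Postn (ENSMUSG00000027750) on chromosome 3 at 54361109 to 54391037. TMM factors would shift all log2 values of the pool by −0.15 at 1d and −0.35 at 7d.

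Among single genes of the pool at 7d, Tsc22d3, a target of glucocorticoids, was at 10.5 (9.44 to 11.7) and Lpl, a lipase, at 6.73 (5.57 to 8.13). The receptor gene Mrgpre was at 17.1 (6.66 to 49.2; 16 UMIs against 7), the kinase complex gene Prr5 at 10.7 and Gask1a at 12.9. Lower genes were the chromatin gene Hmga2 at 0.0118 (1 against 633), a leading gene of cluster 25 with a ratio of up to 0.146 under alternatives, and the cytokine Lif at 0.0370 (7 against 1417). Over the alternatives Tsc22d3 went down to 6.67, Lpl to 3.82, Prr5 to 3.58 and Gask1a to 7.77, and Lif ranged from 0.00638 to 0.0949. The osteocalcin genes Bglap and Bglap2 were at 0.0162 and 0.0417, but this depended on the removal of doublets: with doublets kept their log2 ratios were 0.11 and 0.066. Tsc22d3 (ENSMUSG00000031431) lies on chromosome X at 140539528 to 140600659, Lpl (ENSMUSG00000015568) on chromosome 8 at 68880491 to 68907448 and Bglap (ENSMUSG00000074483) on chromosome 3 at 88383501 to 88384464.

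The p53 list in the pool of 7d was at −0.31 (−0.49 to −0.12; −1.09 in thinned cells), with Sesn2 at 0.164, Fas at 0.188, Mdm2 at 0.193 and Sesn1 at 3.99. Cdkn1a was at 0.504 (0.462 to 0.550). The senescence list was at −0.99 (−1.87 within cluster 19), with Ccl7 at 0.0753, the niche list at −0.17 (−1.35 within cluster 19), with Jag1 at 0.361 and Flt3l at 3.10, and dissociation genes at −0.52, with Hsph1 at 0.205 and Fos at 2.61. Higher lists were G2/M at 1.38 (Cenpf 14.4) and S phase at 0.85 (Dtl 3.56), but over members with at least 100 UMIs these were 0.34 and 0.039. Few pool cells of 7d were cycling, and whether single cells held most UMIs of these 2 lists was not tested. Also higher were DNA repair at 0.54 (Ddb2 3.74; 0.19 with TMM factors), osteogenic at 0.34 (−0.0059 with TMM factors) and mitochondrially encoded genes at 0.29 (mt-Nd6 2.55), the last at −0.058 with TMM factors and −0.051 within cluster 19. The interferon list was at 0.70, with Rsad2 at 9.92, but at −1.25 within cluster 19 alone. Adipogenic (0.14), apoptosis (0.14) and glycolysis (0.15) genes, with Hk2 at 0.124, depended on the setting: they went down to −0.21, −0.91 and −0.53 under alternatives. Cxcl12 was at 0.910 (0.782 to 1.05; 0.379 within cluster 19), Lepr at 1.70 (1.12 to 2.51) and Runx2 at 1.06. Pparg had 0 UMIs against 52, 2.32-fold lower at a floor of 3 UMIs, with an interval from 1.82.

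Genes of taurine handling in the pool were mostly higher at 7d, but not the transporter Slc6a6. The list was at 0.16 in 1d, with 8 of 14 genes measured, and at 0.69 (0.41 to 0.97) in 7d, with 7 of 8 higher. The taurine transporter Slc6a6 (ENSMUSG00000030096, chromosome 6, 91684053 to 91759066) was at 0.932 (0.827 to 1.05) and 0.842 (0.697 to 1.01; 0.364 within cluster 19). Cdo1, which makes cysteine sulfinate, was at 1.22 (0.958 to 1.54) and 1.69 (1.24 to 2.28). With TMM factors Cdo1 was at 1.10 and 1.33, and in thinned cells at 2.29 and 3.07. Csad, which makes hypotaurine, was at 1.22 (0.979 to 1.51) and 1.51 (1.12 to 1.9996), the last at 1.02 in thinned cells. Ggt7 was at 2.67 and Slc36a1 at 2.19 in 7d.

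Genes of the answer to oxidative stress were lower in the pool of 7d. The NRF2 list was at −0.03 in 1d and −0.25 (−0.60 to −0.13; −0.71 in thinned cells) in 7d. Hmox1, haem oxygenase (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), was at 0.607 (0.571 to 0.644) and 0.0835 (0.0649 to 0.106; up to 0.135 under alternatives), and Nfe2l2, which encodes NRF2, at 0.864 and 0.394. The mitochondrial dismutase Sod2 was at 1.33 (1.24 to 1.43) in 1d, with a log2 ratio of −0.43 within cluster 19 alone, and 0.229 (0.180 to 0.287) in 7d. The cystine transporter Slc7a11 was at 0.488 and 0.0311, and Txnrd1 and Srxn1, which restore oxidised proteins, were at 0.0973 and 0.1001 in 7d.

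B cells of 1d held far more Rag1, Gfra1 and Col5a3 than those of Ctrl, with most of them in cluster 6. Rag1, which cuts antigen receptor genes (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501), was at 559.5 (989 against 2 UMIs) and Gfra1 at 296 (262 against 1). Col5a3 (338 against 0) was 127-fold higher at a floor of 3 UMIs, with an interval from 103. MHC class II genes were at −1.26, with 13 of 14 lower, among them H2-Ab1 at 0.310 and Cd86 at 0.309, but at −0.036 with doublets kept and −0.055 within cluster 0 alone. P2ry10 was at 0.228, the kinase Fyn at 0.266 and Cables1 at 0.214, which became 0.624, 0.739 and 0.563 within cluster 0 alone, while interferon genes were at 0.45. B cells of 7d carried more Txnip (6.52), Myadm (6.66) and Rhob (4.57), and less Cables1 (0.110), Stat3 (0.228) and the chemokine receptor Ccr6 (0.159), with interferon genes at −0.66, MHC class II genes at −0.03 and p53 targets at −0.19.

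Neutrophils of 1d had lower p53 targets, interferon and NF-kB genes than those of Ctrl. Ccng1 was at 0.0904, Ifi27l2a, an interferon gene, at 0.137 and Wfdc17 at 0.237, while the complement regulator Cd55 was at 3.04, Krt83 at 2.36 and the sterol factor Srebf2 at 2.501. Over the alternatives Ifi27l2a ranged from 0.0619 to 0.433, Wfdc17 from 0.0978 to 0.364 and Cd55 from 2.78 to 7.08. The interferon list was at −0.72 (−1.50 with no filter) and the NF-kB list at −0.64 (−1.60 with no filter, −0.18 within cluster 1, the best shared one). Cluster 10, with Krt83 among its leading genes, held 244 of 2932 neutrophils in Ctrl, 292 of 665 in 1d and 90 of 227 in 7d. Neutrophils of 7d had more Rab3d (9.10), Myadm (7.79) and Nr4a1 (5.96) and less of the chemokine Cxcl3 (0.0492), Spp1 (0.162) and Upp1 (0.138), which went down to 0.0230, 0.0137 and 0.0476 over the alternatives, while Myadm ranged from 3.76 to 19.2. In the same cells p53 targets were at −0.81 (0.61 within cluster 1 alone), NF-kB genes at −0.92 (−0.14 within cluster 1) and interferon genes at −0.54. Neutrophil precursors lay in clusters 7, 8 and 13, with 107, 41 and 30 cells in Ctrl, 580, 450 and 152 in 1d and 133, 230 and 284 in 7d. They had S phase genes at 0.42 and 0.58 (0.13 at 1d in thinned cells and 0.30 at 7d with TMM factors), G2/M genes at −0.04 and −0.09, NRF2 genes at −0.28 and 0.52 (0.10 with no filter), and p53 targets at −1.14 in 7d.

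T cells of 1d had more Il1rl1, the receptor of interleukin 33 (4.57), Lmo4 (3.74) and the heat shock gene Hspa1a (3.02), and less Trib2 (0.356), Tnfrsf26 (0.405) and Atp9b (0.327). Cluster 11, led by Ctla4 and Icos, held 280 of 1314 T cells in Ctrl, 60 of 168 in 1d and 244 of 1888 in 7d. Within cluster 3, the best shared one, Lmo4 was at 0.981, Hspa1a at 2.33 and Trib2 at 0.175, and in thinned cells Atp9b was at 0.639. T cells of 7d had more Klf10 (6.43), Txnip (4.54) and Klf4 (4.13), and less Elovl6 (0.0415; 0.226 within cluster 3), Tnfrsf18 (0.238) and Ramp3 (0.249). Dissociation genes were higher in T cells at both points, at 0.58 with 26 of 26 genes higher (0.26 within cluster 3) and at 0.75, and in NK cells they were at −0.47 and 0.69. In B cells they were at 0.11, with values from −0.42 to 0.27 over the alternatives, and at 0.86. Targets of p53 in 7d were at 0.03 in T cells, −0.35 in NK cells, −0.67 in monocytes, −0.52 in conventional dendritic cells, −0.51 in mast cells, −0.48 in ligament and tendon cells and −0.15 in macrophages. The mast cell value was 0.060 in thinned cells, and the macrophage value went up to 0.20 under alternatives.

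Compared to 1d, the library labelled 7d held more T cells (8.997-fold, 7.68 to 10.6) and NK cells (18.2-fold, 13.6 to 24.9). Neutrophil precursors were at 0.438 (0.398 to 0.483), B cell precursors at 0.387 (0.313 to 0.477) and the pool at 0.324 (0.2496 to 0.417). Erythroid cells, a class most affected by the filter on barcodes, were at 3.05, and stem and progenitor cells at 1.19 (0.926 to 1.53). In the pool the matrix list was at 1.18, NF-kB genes at −1.32 and p53 targets at 0.35 (0.19 to 0.72), but the last was −0.081 over members with at least 100 UMIs. Over the alternatives the matrix list ranged from 0.84 to 1.19 and NF-kB genes from −2.03 to −1.18.

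Cycling cells were frequent among B cell precursors, at 52.5% in 1d and 16.9% in 7d, and among erythroid cells, at 44.0% and 43.6%. Neutrophil precursors had 12.5%, 12.97% and 13.6% in Ctrl, 1d and 7d, and monocytes 4.76%, 15.6% and 7.33%. Within the neutrophil precursors, cluster 7 had 9.18%, 0.519% and 0 of 129, cluster 8 had 17.1%, 29.8% and 27.9%, and cluster 13 had 17.2%, 10.5% and 8.13%. Of the 54 cycling monocytes of 1d, 50 were in cluster 14, which held 20 of 89, 167 of 353 and 251 of 562 monocytes. Without thinning, neutrophil precursors had 51.7%, 49.2% and 70.0%, monocytes 19.1%, 53.3% and 45.2%, and B cell precursors 78.6% in 1d and 56.6% in 7d. The pool had 0.480%, 0 of 193 and 1.15%, near the 0.298%, 0 and 0 of mature neutrophils. Thinning left out 10, 2 and 6 neutrophil precursors and 18, 22 and 0 pool cells as too shallow.

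RNA of other cells was found in lymphocytes of every library. Hbb-bs, a haemoglobin gene, was detected in 64.6%, 53.6% and 81.6% of T cells and 62.0%, 48.0% and 76.2% of B cells of Ctrl, 1d and 7d. S100a8, a neutrophil gene, was detected in 45.7%, 74.4% and 28.0% of T cells, which had a median of 3191, 3914.5 and 3343 UMIs.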

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

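Several results at 1d and 7d pointed in opposite directions compared to Ctrl, and the differences between the time points were not tested. The NK and innate lymphoid share was 0.152 times that of Ctrl in the library labelled 1d and 2.76 times in the library labelled 7d, and the T cell share 0.225 and 2.02 times. The interferon list in B cells had a median log2 ratio of 0.45 at 1d and −0.66 at 7d. The NRF2 list in neutrophil precursors was −0.28 and 0.52. Dissociation and immediate early genes were −0.47 and 0.69 in NK cells, but 0.22 and −0.52 in the mesenchymal pool, where the value at 1d became −0.013 in thinned cells and −0.031 within cluster 19 alone. The osteogenic list in the pool was −0.14 and 0.34, but 0.065 at 1d in thinned cells and −0.0059 at 7d with TMM factors, so its opposite directions depend on the setting.

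Cells with at least 50 UMIs of Bglap and Bglap2 together were removed as doublets unevenly. The removal took 0 of 40 such cells in Ctrl, 7 of 18 in 1d and 6 of 8 in 7d. With doublets kept, the log2 ratio of Bglap at 7d compared to Ctrl was 0.11 instead of −5.95.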

How the results depend on the processing

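No paired analysis was possible because each group had 1 library, and no library could be left out in turn. Shares gave 158 values under alternatives, of which 121 stayed inside the interval, 33 moved and 4 reversed. Single genes gave 689 values (547 inside, 136 moved, 6 reversed) and lists gave 947 (736, 186 and 25). Of 22 cycling values, 20 moved. Directions set beyond the interval were kept in 147 of 151 share values, 603 of 609 gene values and 696 of 721 list values. The p53 list of the pool in 1d compared to Ctrl ranged from −1.17 to −0.98 over 11 alternatives. All values below are log2, the value of the chosen analysis is in brackets, and the cause was not tested.

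At Leiden resolution 0.5 the macrophage interferon list at 7d compared to Ctrl was −0.48 (1.29), and the neutrophil share was −0.50 (−1.32) at 1d and −2.65 (−3.20) at 7d. At resolution 2 the neutrophil share at 1d was −1.19. With the stricter filter it was −1.13. With no filter the neutrophil share was −0.32 at 1d and −2.44 at 7d, the erythroid share −0.48 (4.26) at 1d and −0.035 (5.87) at 7d, the macrophage share at 7d 0.10 (−2.84) and the macrophage interferon list at 7d −0.028. With neutrophil, neutrophil precursor and erythroid cells left out of the denominator, the T cell share at 7d was 0.70 (1.02).

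With doublets kept, the B cell share at 1d was −1.56 (0.27), the neutrophil share at 1d −1.18 and the B cell p53 list at 1d −0.23 (0.30). In the pool at 1d the haemoglobin list was 0.23 (−3.34), the MHC class II list 0.76 (−0.75) and the granule list 0.58 (−0.42). In the pool at 7d Bglap was 0.11 (−5.95), Bglap2 0.066 (−4.58) and the matrix list 0.74 (1.07).

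With TMM factors, pool lists at 1d were −0.030 (0.12) for adipogenic and −0.038 (0.11) for glycolysis genes. At 7d they were 0.73 for matrix, −0.058 (0.29) for mitochondrially encoded, −0.0059 (0.34) for osteogenic, 0.34 (0.69) for taurine and −0.66 (−0.31) for p53 genes.

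With each cell thinned, pool lists at 1d were −0.016 for adipogenic, −0.013 (0.22) for dissociation, −0.064 for glycolysis, 0.26 for granule and 0.065 (−0.14) for osteogenic genes. At 7d they were 0.93 for matrix, −0.28 (0.70) for interferon, −0.71 (−0.25) for NRF2 and −1.09 for p53 genes, and the mast cell p53 list was 0.060 (−0.51). With members of at least 100 UMIs, the pool p53 list in 7d compared to 1d was −0.081 (0.35).

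Within the best shared cluster alone, an alternative added after the data were seen, pool values at 1d were −0.43 (0.41) for Sod2, −0.25 for adipogenic, −0.031 for dissociation and 2.32 for granule genes. At 7d they were 0.36 for Bglap, 0.20 for Bglap2, 0.79 for matrix, −1.25 for interferon and −0.051 for mitochondrially encoded genes. The p53 list was −0.37 in B cells at 1d and 0.61 (−0.81) in neutrophils at 7d, and Lmo4 in T cells at 1d was −0.028 (1.90).

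Several alternatives gave no value. These were the B cell precursor share ratios (0 in Ctrl) under most settings, the stem and progenitor share under the stricter filter, no filter and the clustering without p53, interferon and dissociation genes, the erythroid share under the stricter filter, the conventional dendritic share under no filter and the monocyte share at resolution 0.5. The periodontal ligament and tendon share had none under the stricter filter, doublets kept and resolution 0.5, and its p53 list at 1d none at resolution 2. Macrophage lists at 7d had none at resolution 2. Rag1 and Gfra1 in B cells had none with doublets kept, thinned cells or the shared cluster. Col5a3 in B cells and Pparg in the pool at 7d had 0 counts on one side. Thinning gave none for the taurine and DNA repair lists, the interferon lists of stem and progenitor and plasmacytoid dendritic cells, the mast cell p53 list at 1d, Psrc1 and Mrgpre. The mast cell p53 list at 1d also had none with members of at least 100 UMIs. The shared cluster gave none for the haemoglobin list, Eda2r, Psrc1, Pparg at 1d, Rab3d and Il1rl1.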

Other observations

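Interferon genes were lower in 7d than in 1d in several classes. The median log2 ratio was −1.37 in B cells, −1.16 in B cell precursors (21 of 26 genes lower), −0.95 in haematopoietic stem and progenitor cells (22 of 24 lower) and −2.18 in plasmacytoid dendritic cells, where all 16 measured genes were lower. Over the alternatives the B cell value ranged from −1.65 to −0.81 and the B cell precursor value from −1.50 to −0.60. B cells lay mostly in cluster 6 at 1d (888 of 1253) and in cluster 0 at 7d (363 of 495). G2/M genes were also lower in B cell precursors at 7d, at −0.78 with 50 of 52 genes lower (−0.21 with doublets kept). In erythroid cells p53 targets went the other way, at 0.49, but at 0.072 over members with at least 5 UMIs. Macrophages of 7d held higher interferon genes than those of Ctrl (1.29), but at Leiden resolution 0.5 the value was −0.48.

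The tests for p53 targets were chosen only after the result was seen. The p53 list was lower in the library labelled 1d than in Ctrl beyond its interval in 8 of 10 classes, although 10 Gy was given to 1d and p53 targets are induced by DNA damage, so an exchange of the labels Ctrl and 1d may be the cause. A shift in the makeup of classes would leave single clusters level, but 15 of 19 clusters were lower beyond their intervals and 0 were higher beyond them. Free RNA alone would give every class the same ratio of Ccng1 to Cdkn1a, but in Ctrl that ratio was 7.20-fold higher in B cells than in endothelial cells. Free RNA on top of each class's own RNA could also give differing ratios, so a contribution of free RNA stays open. B cells were the exception at 0.30, and within their best shared cluster the value was −0.37. In 7d compared to Ctrl the p53 list was lower beyond its interval in 7 of 10 classes and higher in 0. In 7d compared to 1d it was higher beyond its interval in 6 of 14 classes and lower in 3. T cells (0.225 of Ctrl), NK cells (0.152) and the pool (0.588) were scarcer in 1d, as the labels given could have it. However, T and NK cells were most frequent in 7d (2.02 and 2.76 times Ctrl), so their shares do not decide between the labels. A true fall of p53 targets 1 day after irradiation was not tested.

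The tests for B cell precursors were chosen only after the result was seen, except the test of the filters. Less marrow in the Ctrl suspension could lower every marrow class, but the interval of the B cell precursor ratio of 1d over Ctrl started at 133. That lay above the upper ends for stem and progenitor cells (10.4) and neutrophil precursors (13.8). These other classes and monocytes were also scarcer in Ctrl, so less marrow as a part of the cause stays open. The filters did not remove B cell precursors, since 12 Ctrl barcodes carried at least 2 UMIs of 4 precursor genes before filtering and 11 after it. By that count 1d held 543 kept cells, so the interval from 133 is for the named cluster alone and not for every cell with precursor genes. An exchange of the labels Ctrl and 1d may be the cause, because B cell precursors die readily after irradiation and they made up 5.76% of 1d, more than the 2.23% of 7d. T cells (0.225 of Ctrl) and NK cells (0.152), also lymphoid, were scarce in the library labelled 1d. Both were most frequent in 7d (2.02 and 2.76 times Ctrl), which came after irradiation under either labelling. Their shares therefore do not decide between the labels, and the cause stays open.

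The tests for matrix and inflammatory genes at 7d were chosen only after the result was seen. The makeup of the pool could raise matrix genes if ligament cells made up more of it, but within the periodontal ligament and tendon cluster alone the matrix list was still at 0.79 and the NF-kB list at −1.96. Less handling stress in 7d as a whole could lower NF-kB genes, but dissociation genes were higher at 7d in 3 of 3 lymphoid classes, although lower in the pool itself (−0.52, and −0.87 to −0.13 over the alternatives), so stress particular to the pool stays open. A change in the state of the ligament cells themselves after irradiation may remain, and 1 library per group leaves it open.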
